A study of Homo sapiens with 18 samples.

How the data were processed

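RNA was measured in 18 libraries of cell lines labelled XG1 and AMO1, in 6 groups of 3 replicates (DMSO, 100 nM or 1000 nM YKL-5-124 for 6 h). Per the labels' protocols the cells grew in multiwell plates in RPMI with fetal bovine serum, were lysed in TRIzol, their RNA was purified on columns, and libraries were made by the QuantSeq method, which reads the 3′ ends of polyadenylated transcripts. Groups and replicate numbers came from the labels. Per the submitters' processing notes the authors used HISAT2, Cuffnorm and the genome build hg19; versions, the gene annotation, read counts and whether counting used strand are not given in the sources used here. The deposited values, 1 table of gene symbols and expression values per library, are FPKM (fragments scaled to transcript length and library size), a unit taken from the name of Cuffnorm in those notes, since the file headers say only that the values are expression. FPKM divides by transcript length, which does not set the read number of a 3′ end library, so levels of different genes are not comparable as molecules, while changes of 1 gene between libraries are.

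The tables held 26249 genes and 92 ERCC spike-in RNAs, synthetic RNAs of known amount. No value was 0. The commonest low value of a library, its floor, lay between 0.0745 and 0.1333 FPKM, and some genes lay below it. CIITA, for example, was at 0.0678 FPKM in XG1 1000 nM replicate 2, whose floor was 0.081. Values near the floor in one line also differed with a gene's level in the other, a difference whose cause was not tested. Genes under 0.15 FPKM in all 9 XG1 libraries were divided by their AMO1 level. The 7312 below 0.125 FPKM in AMO1 had a median XG1 log2 of -3.27, and the 29 at 4 FPKM or more had -3.35. Over 44 spike-ins with a log2 above 3 in every library the libraries' median deviations lay between -0.08 and 0.07 log2. Between the lines these spike-ins differed with an SD of 0.55 log2 (-1.36 to 1.05, 4 of them over 2-fold), beside a median SD of 0.139 and 0.143 within a line, so differences between the lines carry an error that the replicates do not show. The depth of each library is unknown because the values are not counts and show no whole steps, so no counting interval or detection limit could be set, and no count model was used. A library had 9284 to 10571 genes at 1 FPKM or more, and log2 values correlated at 0.955 to 0.974 within groups across genes. No library pair was identical.

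Genes with a mean of at least 1 FPKM in at least 1 group were tested, 12204 in all. The test was limma 3.58.1 (R 4.3.3, statmod 1.5.0) with trend and robust estimation on log2(FPKM + 1), 1 mean per group over all 18 libraries in 1 fit, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 9 comparisons were each dose against DMSO and 1000 against 100 nM in each line, the difference of the lines' responses at each dose, and XG1 against AMO1 in DMSO. Genes were named by a rule fixed before the data were examined: the 10 largest rises and falls per DMSO comparison (5 for the other comparisons) among called genes whose groups did not overlap, which chance alone gives in 10% of comparisons of 3 with 3, up to 3 called members per direction of each gene list, and CDK7, CCNH, MNAT1, MYC, IRF4, E2F1, CDKN1A, MCL1 and ABCB1. Small RNA, ribosomal RNA and uncharacterised loci were counted but not named. Genes named outside the rule are said to be so. Some results for genes that the rule names are not reported here.

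Before the data were examined 21 gene lists were fixed from general knowledge, and 20 had tested members. They held E2F and G1/S, G2/M and mitosis, MYC target, myeloma and plasma cell, p53 target, immediate early, DNA repair, transcription CDK and TFIIH, unfolded protein and amino acid stress, glycolysis, apoptosis regulator, NF-kappaB target, interferon response, cholesterol synthesis, heat shock, ribosomal protein, mitochondrial respiration, drug transporter, T cell and myeloid marker, and stromal and epithelial marker genes. The last list, mitochondrially encoded transcripts, meant as a sign of RNA quality, had 0 of its 13 symbols in the tables used here. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment within a comparison. Camera compares a list with the other genes, and fry asks whether its members move one way on balance. Called members were counted over all genes and adjusted over the list alone. After the data were examined 7 further lists were written (erythroid, plasma cell, antigen presentation, snoRNA host, RNA splicing factor, ATF4 pathway, and tRNA modification and ribosome assembly genes).

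Overlaps of calls were set beside those of independent lists and, for doses that share DMSO libraries, beside 50 simulations of unchanged groups. The tests were tried on simulated independent noise without library shifts, with 200 of 12204 genes changed. Over 20 draws, 70% to 86% of 2-fold and 92% to 100% of 4-fold changes were recovered in XG1 at 100 nM, and 72% to 90% and 91% to 99% in AMO1. At 1000 nM these were 74% to 87% and 91% to 99% in XG1 and 71% to 85% and 94% to 100% in AMO1. For the difference of the responses they were 25% to 45% and 88% to 96% at 100 nM and 30% to 49% and 90% to 98% at 1000 nM. False calls made up 0.588% to 8.89% of calls in a draw. These rates need not hold for the real libraries. The alternatives tried were a pseudocount of 0.1 or 5, no filter or a minimum mean of 5 FPKM, centring each library on its median within its line, quantile normalization, scaling to the spike-ins, a fit without trend and robust estimation, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. Gene spans came from another genome build than hg19, so no coordinates are given.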

Results

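Transcript levels were measured by 3′ end RNA sequencing in 18 libraries from cultures labelled as the human multiple myeloma lines XG1 and AMO1. Multiple myeloma is a cancer of antibody-secreting plasma cells. The series title names resistant myeloma lines and inhibition of CDK7, the kinase that phosphorylates RNA polymerase II within TFIIH and activates cell cycle kinases. The cells of each line had been treated for 6 h with DMSO, the solvent, or with 100 or 1000 nM YKL-5-124, a covalent CDK7 inhibitor. This gave 6 groups of 3 libraries. Expression was given in FPKM for 26249 genes, and 9284 to 10571 of these were at 1 FPKM or more in a library. The values came without read counts, so the depth behind them is unknown and no counting interval is given. Levels are means ± SD over 3 libraries. Log2 changes are on the log2(FPKM + 1) scale with their SE and understate the change of low genes. Adjusted p values are from limma over the 12204 genes tested. The labels do not say that replicates were separate cultures, so each p measures only the spread between these libraries, which may be technical.

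The first comparison asked how the DMSO-treated libraries of the lines differed before any inhibitor was added. Genes of plasma cell identity were abundant in AMO1 and far lower in the libraries labelled XG1. JCHAIN, the joining chain of polymeric antibodies, was at 2.77 ± 0.349 against 1206 ± 165 FPKM in XG1 against AMO1 (log2 difference -8.32 ± 0.25, adjusted p = 9.32e-16). IRF4, a transcription factor on which myeloma cells depend, was at 0.171 ± 0.0442 against 32.8 ± 1.30 FPKM (-4.85 ± 0.15, adjusted p = 5.69e-16), and HLA-DRA, an antigen presentation gene, was at 0.280 ± 0.0641 against 424 ± 59.6 FPKM (-8.37 ± 0.18, adjusted p = 6.78e-18). Higher in the libraries labelled XG1 were the fetal hemoglobin gene HBG1, at 1265 ± 118 against 2.11 ± 1.03 FPKM (8.72 ± 0.62, adjusted p = 4.98e-08). So was GYPB, a red cell surface glycophorin, at 1071 ± 77.0 against 1.11 ± 1.14 FPKM (9.13 ± 0.43, adjusted p = 1.21e-10). GAL (8.45 ± 0.45) and HINT1 (8.60 ± 0.63) were also higher in XG1, and CTAG2, a cancer-testis antigen (-9.04 ± 0.51), was lower. In limma, 7652 of 12204 genes differed, 3458 higher and 4194 lower in XG1, and 1784 and 2373 of them by 2-fold or more. After quantile normalization the higher and lower counts were 4236 and 3970.

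Of the genes named in advance, CDKN1A, a cell cycle inhibitor, was at 0.745 ± 0.128 against 208 ± 68.3 FPKM in XG1 against AMO1 (-6.84 ± 0.24, adjusted p = 2.41e-15). MCL1, a survival factor of plasma cells, was at 89.8 ± 12.2 against 578 ± 74.4 FPKM (-2.67 ± 0.15, adjusted p = 3.55e-12). E2F1 (-1.42 ± 0.25, adjusted p = 4.14e-05) and ABCB1, a drug efflux pump (-1.56 ± 0.20, adjusted p = 9.70e-07), were lower in XG1. CDK7 itself was at 14.97 ± 2.81 against 12.0 ± 2.65 FPKM (log2 difference 0.30 ± 0.20, adjusted p = 0.193). Its partner MNAT1 was at 12.8 ± 2.65 against 9.34 ± 2.10 FPKM (0.42 ± 0.26, adjusted p = 0.162). Neither was called, though MNAT1 was after quantile normalization (0.55, adjusted p = 0.0282). MYC, at 59.0 ± 20.6 against 41.6 ± 18.01 FPKM (0.51 ± 0.29, adjusted p = 0.135), was not called either. It was called higher in XG1 after quantile normalization (0.78, adjusted p = 0.0388) and without DMSO replicate 3 of XG1 (0.81, 0.0217) or AMO1 (0.83, 0.0149). CCNH, the cyclin of CDK7, was called higher in XG1 (0.72 ± 0.28, adjusted p = 0.0339). That call ended without DMSO replicate 1 or 2 of either line, where the adjusted p reached 0.0985, and without the filter on low genes (adjusted p = 0.0578).

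Lists written after these levels were seen described the lines further. Of 10 plasma cell genes, 9 were at 10 FPKM or more in all 9 AMO1 libraries, 5 were under 1 FPKM in all 9 libraries labelled XG1, and the median log2 difference was -5.65. SDC1, the plasma cell surface marker CD138, was at 12.1 ± 2.22 against 4004 ± 798 FPKM, XG1 given first. TNFRSF17, which encodes BCMA, was at 0.883 ± 0.118 against 164 ± 13.4 FPKM. Of 18 erythroid genes, leaving out KLF1 and HEMGN, which had prompted the list, 12 were at 10 FPKM or more in all 9 libraries labelled XG1. Of these, 5 were under 1 FPKM in all 9 AMO1 libraries, and 1 of the 18 was at 10 FPKM or more in all AMO1 libraries. HBG1 and GYPB, whose levels had been seen before, count among the 12. GATA1, the main erythroid transcription factor, was at 28.5 ± 1.93 against 0.117 ± 0.0196 FPKM, and the alpha globin gene HBA2 at 493 ± 30.4 against 0.813 ± 0.621 FPKM. Because these levels go against what the label XG1 names, the group is called the libraries labelled XG1, or XG1 libraries for short, and every direction given for it is that of these libraries.

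**Figure D1:**
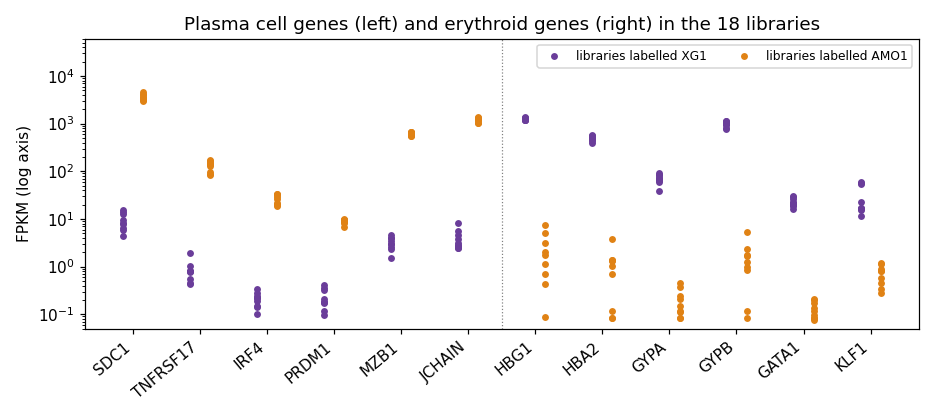
Expression in FPKM (log axis) of 6 plasma cell genes and 6 erythroid genes in the 18 libraries, each point being 1 library, colored by cell line label. JCHAIN was at 2.77 ± 0.349 against 1206 ± 165 FPKM and HBG1 at 1265 ± 118 against 2.11 ± 1.03 FPKM in DMSO, the libraries labelled XG1 given first and AMO1 second.

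In the XG1 libraries at 100 nM against DMSO, SNHG12, a host gene of small nucleolar RNAs, fell from 75.4 ± 7.87 to 16.7 ± 2.46 FPKM (log2 change -2.11 ± 0.20, adjusted p = 8.18e-06). METTL1, a tRNA methyltransferase, fell from 35.9 ± 2.24 to 9.49 ± 1.71 FPKM (log2 change -1.82 ± 0.19, adjusted p = 9.88e-06). ATF4, the transcription factor of the amino acid stress response, fell from 119 ± 6.27 to 45.7 ± 4.08 FPKM (log2 change -1.37 ± 0.20, adjusted p = 3.24e-04). So did CHAC1, a glutathione-degrading enzyme that ATF4 induces, from 6.08 ± 1.51 to 1.20 ± 0.766 FPKM (log2 change -1.73 ± 0.26, adjusted p = 4.94e-04). HSPA8, a constitutive chaperone, fell from 147 ± 12.3 to 52.9 ± 14.0 FPKM (log2 change -1.49 ± 0.22, adjusted p = 4.24e-04). Risers included KRCC1, from 0.648 ± 0.278 to 10.1 ± 0.7996 FPKM (log2 change 2.77 ± 0.33, adjusted p = 6.03e-05). GDF15, a secreted stress cytokine, rose from 39.4 ± 4.23 to 88.2 ± 4.19 FPKM (log2 change 1.15 ± 0.20, adjusted p = 0.00142).

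Other genes among the largest falls were TEX19 (-2.03), DHRS9 (-1.76), the kinase CDK3 (-1.69) and SNHG3, another host gene of small nucleolar RNAs (-1.67). The largest rises also held HCG17 (2.48), NRN1L (2.43), SMIM14 (2.16), CCDC92 (2.15), MEIG1 (2.03), SDCBP2 (1.79) and the antisense-named ZEB2-AS1 (1.93), SNAI3-AS1 (1.71) and NUP50-AS1 (1.68). Whether counting used strand is not given in the sources used here, so levels of antisense and overlapping genes are uncertain. H3F3AP4, a histone H3.3 pseudogene whose reads can be shared with near-identical copies (-7.28), VTRNA2-1 (-2.09) and SAPCD1 (-1.68) were called too, but those calls ended without single libraries. These were DMSO replicate 1 or 3 or 100 nM replicate 1 or 3 for H3F3AP4 (adjusted p up to 0.0534), DMSO replicate 1 or 2 for VTRNA2-1 (up to 0.133), and DMSO replicate 2 or 3 or 100 nM replicate 1 or 2 for SAPCD1 (up to 0.0742). With only the 6 libraries compared in the fit, VTRNA2-1 (adjusted p = 0.258) and SAPCD1 (0.105) were not called, nor was SAPCD1 with a pseudocount of 0.1 (0.0645).

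MYC fell from 59.0 ± 20.6 to 26.5 ± 0.196 FPKM (log2 change -1.06 ± 0.29, adjusted p = 0.0341). E2F1 fell from 7.36 ± 0.862 to 3.497 ± 0.987 FPKM (log2 change -0.91 ± 0.25, adjusted p = 0.0293). The MYC call ended without DMSO replicate 1 or 2 or any 100 nM replicate (adjusted p up to 0.147), without the filter (0.0588) and with spike-in scaling (0.0514). The E2F1 call ended without any DMSO replicate or 100 nM replicate 2 or 3 (up to 0.107), with a pseudocount of 5 (0.0753) and without the filter (0.0577). CDK7 went from 14.97 ± 2.81 to 10.5 ± 1.17 FPKM (log2 change -0.47 ± 0.20, adjusted p = 0.178), which was not called. MCL1 went from 89.8 ± 12.2 to 123 ± 9.55 FPKM (log2 change 0.46 ± 0.15, adjusted p = 0.0737), also not called. It was called higher after centring each library on its median (0.48, adjusted p = 0.0165), after quantile normalization (0.63, 0.00195) and without AMO1 DMSO replicate 3, whose removal changes the pooled spread (0.0276). CCNH (0.12, adjusted p = 0.894) and MNAT1 (0.23, adjusted p = 0.691) were not called, and IRF4, CDKN1A and ABCB1 were under 1 FPKM in both groups.

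By gene list, 10 of 35 E2F and G1/S genes fell and 25 were not called (19 lower adjusted over the list alone), with UNG (-0.94), RRM2 (-0.85) and PCNA (-1.03) among those that fell. The list averaged -0.43 log2 against other genes (camera adjusted p = 1.12e-09). MYC target genes followed with 6 of 29 lower (10 adjusted over the list alone), among them the nucleolar genes GNL3 (-1.09) and PPAN (-0.76), at -0.35 (adjusted p = 2.70e-07). Of the unfolded protein and amino acid stress genes, 6 of 21 fell (8 adjusted over the list alone), DDIT3 (-0.98) with ATF4 and CHAC1, at -0.36 (adjusted p = 6.47e-04). Of the G2/M and mitosis genes 5 of 28 fell (7 adjusted over the list alone), including TOP2A (-0.87), at -0.26 (adjusted p = 4.19e-04). Of the DNA repair genes 5 of 19 fell (7 adjusted over the list alone), including EXO1 (-0.94) and the mismatch repair gene MSH6 (-0.79), at -0.36 (adjusted p = 4.19e-04). All 5 calls at camera's preset correlation were lost (adjusted p = 0.646 with an estimated correlation), but fry called 4 of them.

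The 15 other lists were not called by camera. Mitochondrial respiration genes were called higher after centring (adjusted p = 0.0432), after quantile normalization (0.00723), with a pseudocount of 5 (0.0362), with a minimum mean of 5 FPKM (0.0240), without the filter (0.0292) and without 100 nM replicate 1 (0.0242). Without the filter cholesterol synthesis (0.0347) and heat shock genes (0.0287) were called lower. Immediate early genes held 3 that rose, EGR1 (1.19) and JUNB (0.90) among them, and 1 that fell of 20 (4 and 1 adjusted over the list alone). The p53 target genes held 2 that rose, GDF15 and BTG2 (1.24), and 3 that fell of 22 (2 and 4). Of 25 transcription CDK and TFIIH genes, POLR2A, the largest subunit of RNA polymerase II, rose (0.90) and 2 fell, including CDK12 (-1.03), a kinase of elongating polymerase (3 and 2 adjusted over the list alone). Lower were 4 of 19 cholesterol synthesis genes, such as SQLE (-1.07), and 2 of 14 interferon response genes, such as IFIT3 (-1.20). Heat shock genes had 1 higher and 2 lower of 16.

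Over all genes, limma called 807 in the XG1 libraries at 100 nM, 321 higher and 486 lower, with 98 and 101 by 2-fold or more. The split moved with scaling, to 695 higher and 898 lower when each library was centred on its median and to 892 and 986 after quantile normalization. It was 203 and 462 among genes with a group mean of 5 FPKM or more. The count fell to 396 without DMSO replicate 2, 465 without DMSO replicate 1, 524 without DMSO replicate 3, 416 without 100 nM replicate 1 and 464 without 100 nM replicate 3.

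In the XG1 libraries at 1000 nM against the same DMSO libraries, SNHG12 fell from 75.4 ± 7.87 to 13.7 ± 3.89 FPKM (log2 change -2.41 ± 0.20, -2.21 after centring, adjusted p = 8.56e-07). METTL1 fell from 35.9 ± 2.24 to 7.67 ± 1.15 FPKM (log2 change -2.09 ± 0.19, -1.89 after centring, adjusted p = 1.61e-06). MYC fell from 59.0 ± 20.6 to 15.8 ± 5.69 FPKM (log2 change -1.84 ± 0.29, -1.63 after centring, adjusted p = 4.10e-04), and E2F1 fell from 7.36 ± 0.862 to 2.57 ± 0.661 FPKM (log2 change -1.24 ± 0.25, -1.04 after centring, adjusted p = 0.00184). PCNA, the sliding clamp of DNA replication, fell from 151 ± 27.4 to 41.9 ± 11.4 FPKM (log2 change -1.85 ± 0.20, -1.64 after centring, adjusted p = 6.09e-06). EGR1, an immediate early transcription factor, rose from 17.9 ± 2.06 to 70.2 ± 9.49 FPKM (log2 change 1.91 ± 0.25, 2.11 after centring, adjusted p = 3.80e-05). HIST1H3D, a histone H3 gene, rose from 4.85 ± 2.28 to 19.9 ± 1.501 FPKM (log2 change 1.91 ± 0.22, 2.12 after centring, adjusted p = 1.13e-05).

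Centring is given beside these changes because the median log2 change of all genes was -0.19 at this dose and 0.01 after each library was centred on its median. Other large falls, main value first and centred value second, were CHAC1 (-2.29, -2.08), GBGT1 (-2.27, -2.06), TEX19 (-2.09, -1.89), SNHG3 (-2.06, -1.86), DHRS9 (-2.01, -1.801) and SAPCD1 (-2.50, -2.30). Other large rises were SDCBP2 (2.11, 2.32), HCG17 (2.10, 2.30), CCDC92 (2.08, 2.29), NRN1L (2.04, 2.25), KRCC1 (1.97, 2.17) and ALDH8A1 (1.84, 2.04). CDK7 itself fell from 14.97 ± 2.81 to 8.27 ± 1.97 FPKM (log2 change -0.79 ± 0.20, -0.59 after centring, adjusted p = 0.00945). That call ended without DMSO replicate 1 (adjusted p = 0.0661) and after quantile normalization (0.0766). CCNH (-0.51, adjusted p = 0.237), MNAT1 (-0.54, 0.157), MCL1 (0.34, 0.122), CDKN1A (-0.14, 0.765), IRF4 (0.14, 0.601) and ABCB1 (0.01, 0.994) were not called. MCL1 was called higher after centring (0.55, adjusted p = 0.00609) and quantile normalization (0.64, 0.00123). CDKN1A turned to 0.07 after centring and ABCB1 to -0.02 with a pseudocount of 0.1.

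Among the lists, 27 of 35 E2F and G1/S genes fell (30 adjusted over the list alone), among them UNG (-1.59) and RRM2 (-1.24). The list averaged -0.59 log2 against other genes (camera adjusted p = 1.29e-12). 15 of 29 MYC target genes fell (19 adjusted over the list alone), such as GNL3 (-1.40) and DKC1 (-0.68), at -0.26 (adjusted p = 2.52e-04). The G2/M and mitosis list had 13 of 28 lower (19 adjusted over the list alone), such as CDK1 (-1.02) and AURKB (-0.89), at -0.31 (adjusted p = 3.36e-04). DNA repair had 10 of 19 (11), such as EXO1 (-1.46) and BRCA1 (-1.11), at -0.45 (adjusted p = 2.52e-04). Unfolded protein and amino acid stress genes had 8 of 21 lower (8 adjusted over the list alone), such as HERPUD1 (-1.45) and DDIT3 (-1.10), at -0.35 (adjusted p = 0.00576). Immediate early genes averaged 0.29 above other genes (adjusted p = 0.00639). Of these, 4 of 20 were higher, JUNB (0.97) and IER3 (0.95) among them, and 3 lower including MYC (4 and 3 adjusted over the list alone). None of the 6 calls held (adjusted p = 0.750 with an estimated correlation), but fry called 5 of them. The immediate early call also ended without 1000 nM replicate 1 (adjusted p = 0.0841) and without the filter (0.0572), and the stress gene call without 1000 nM replicate 3 (0.109).

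Lists not called by camera at this dose included the myeloma and plasma cell genes, with 4 of 24 lower (7 adjusted over the list alone), such as IKZF1 (-0.84) and XBP1 (-0.77). 10 of those 24 genes were below 1 FPKM in the XG1 libraries. Of 22 p53 target genes 2 rose, GDF15 (1.41) and BTG2 (1.07), and 4 fell (2 and 5 adjusted over the list alone), including MDM2 (-0.83) and BBC3 (-0.94). Of the transcription CDK and TFIIH genes, 2 rose and 5 fell, with POLR2A at 0.86 and CDK12 at -1.10. Lower were also 5 of 19 apoptosis regulators such as PMAIP1 (-0.96), 4 of 16 heat shock genes such as HSPA8 (-1.88), 4 of 19 cholesterol synthesis genes such as SQLE (-1.32). So were 3 of 14 interferon response genes such as IFIT3 (-1.10), and 2 of 19 glycolysis genes. Adjusted over the list alone these 5 counts were the same. 2 of 15 NF-kappaB target genes fell (2 adjusted over the list alone). The glycolysis and NF-kappaB shares lay below that of all genes (1920 of 12204), and the myeloma share near it.

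Over all genes, limma called 2152 in the XG1 libraries at 1000 nM, 232 higher and 1920 lower, with 73 and 377 by 2-fold or more. After centring the split was 787 higher and 1245 lower, and after quantile normalization 1174 and 1209, while spike-in scaling gave 232 and 1760. The count was 1108 without DMSO replicate 1, 1335 without DMSO replicate 2 and 1184 without 1000 nM replicate 2, whose median over genes lay -0.32 log2 from that of its line. It was 1197 with only the 6 libraries compared in the fit.

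**Figure D2:**
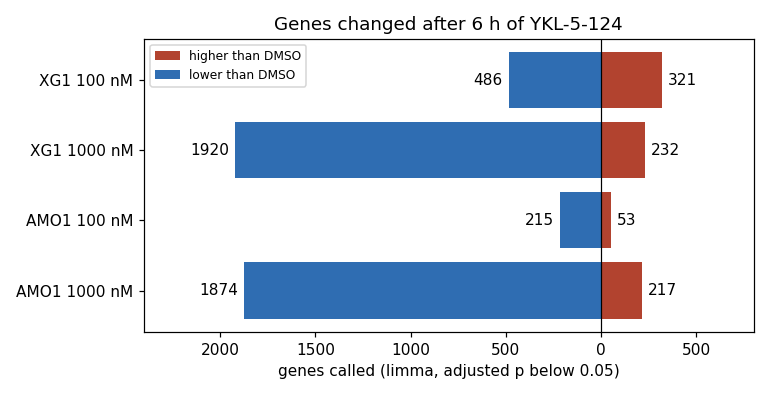
Number of genes called higher or lower than DMSO (horizontal bars, limma adjusted p below 0.05) in each line at each dose, out of 12204 genes. Lower genes outnumbered higher ones in all 4 comparisons, from 215 against 53 in AMO1 at 100 nM to 1920 against 232 in the XG1 libraries at 1000 nM.

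In AMO1 at 100 nM, GDF15 rose from 28.9 ± 9.94 to 104 ± 14.4 FPKM (log2 change 1.87 ± 0.20, 1.97 after centring, adjusted p = 2.20e-05). POLR2A rose from 58.9 ± 15.9 to 181 ± 27.1 FPKM (log2 change 1.63 ± 0.18, 1.73 after centring, adjusted p = 2.41e-05). HIST2H2BE, a histone H2B gene whose transcript is polyadenylated, rose from 4.67 ± 1.81 to 21.02 ± 4.13 FPKM (log2 change 1.99 ± 0.21, 2.10 after centring, adjusted p = 2.20e-05). HNRNPDL and RBM39 encode splicing-related RNA-binding proteins. HNRNPDL fell from 150.4 ± 33.1 to 49.96 ± 4.61 FPKM (log2 change -1.55 ± 0.15, -1.44 after centring, adjusted p = 9.91e-06). RBM39 fell from 161 ± 43.4 to 53.2 ± 6.67 FPKM (log2 change -1.54 ± 0.18, -1.44 after centring, adjusted p = 6.32e-05). SNHG12 fell from 70.9 ± 10.1 to 18.8 ± 3.69 FPKM (log2 change -1.86 ± 0.20, -1.76 after centring, adjusted p = 2.75e-05). TEX19 fell from 27.4 ± 6.56 to 5.96 ± 1.22 FPKM (log2 change -2.02 ± 0.20, -1.91 after centring, adjusted p = 1.61e-05), and HSPA8 fell from 233 ± 34.0 to 93.7 ± 20.4 FPKM (log2 change -1.32 ± 0.22, -1.21 after centring, adjusted p = 0.00271). The centred values are given because the median log2 change of all genes was -0.09 and became 0.02 after centring.

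Also among the largest rises, main value first and centred value second, were UCN (1.63, 1.73), TMEM129 (1.55, 1.66), IER3 (1.41, 1.52), ZNF580 (1.20, 1.31) and BDNF-AS (1.56, 1.67). Large falls included FAM69B (-1.54, -1.44), MGAT3, a glycosyltransferase (-1.47, -1.36), INHBE (-1.42, -1.31) and TAF1D (-1.33, -1.23). The genes named in advance were not called by limma. MYC went from 41.6 ± 18.01 to 22.4 ± 2.70 FPKM (log2 change -0.79 ± 0.29, -0.69 after centring, adjusted p = 0.172). CDK7 went from 12.0 ± 2.65 to 8.03 ± 0.876 FPKM (log2 change -0.51 ± 0.20, -0.41 after centring, adjusted p = 0.2002) and IRF4 from 32.8 ± 1.30 to 24.9 ± 4.41 FPKM (log2 change -0.40 ± 0.15, -0.29 after centring, adjusted p = 0.193). MCL1 (0.33, adjusted p = 0.295), CDKN1A (0.44, 0.412), E2F1 (-0.17, 0.846), ABCB1 (0.12, 0.873), MNAT1 (-0.06, 0.980, and 0.05 and 0.09 after centring and quantile normalization) and CCNH (0.01, 0.997) made up the rest.

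Camera called 6 lists at this dose. The p53 target genes averaged 0.35 log2 above other genes (adjusted p = 2.72e-05), with GDF15 as the 1 of 22 that rose over all genes and 7 higher and 3 lower adjusted over the list alone. 2 of 29 MYC target genes fell (8 adjusted over the list alone), at -0.22 (adjusted p = 1.53e-04). Of the myeloma and plasma cell genes 2 of 24 fell (2 adjusted over the list alone), at -0.19 (adjusted p = 0.0165). Immediate early genes had 2 higher, IER3 among them, and 1 lower of 20 (3 and 1 adjusted over the list alone). They lay 0.19 above other genes (adjusted p = 0.0389, median change -0.02). Ribosomal protein and mitochondrial respiration genes both lay 0.20 above other genes (adjusted p = 1.53e-04 and 5.45e-04). Limma called none of their 32 and 25 members (in either direction, 0 and 1 at an unadjusted p below 0.05). All 6 calls were lost (adjusted p = 0.864 with an estimated correlation), and fry called 0 lists. Calls for 4 lists also ended without single libraries. Those were immediate early genes without DMSO replicate 2 (adjusted p = 0.181) or 100 nM replicate 1 (0.111) or 3 (0.0728), and myeloma genes without DMSO replicate 1 (0.0650) or 100 nM replicate 2 (0.0874). Ribosomal protein (0.128) and respiration genes (0.0913) lost theirs without DMSO replicate 3. Quantile normalization ended the ribosomal protein (adjusted p = 0.687), respiration (0.204) and immediate early (0.0520) calls. The last ended also after centring (0.0763), with a pseudocount of 5 (0.112), without the filter (0.0622) and with a minimum mean of 5 FPKM (0.239). The myeloma call ended with a pseudocount of 0.1 (0.0880) and with only the 6 libraries compared (0.0557).

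In the lists without a camera call, of which DNA repair was called lower without the filter (adjusted p = 0.0353), HERPUD1, an endoplasmic reticulum stress gene, fell from 64.9 ± 6.81 to 30.9 ± 2.74 FPKM (log2 change -1.04 ± 0.17, -0.94 after centring, adjusted p = 0.00180). It was 1 of 2 lower and 1 higher of 21 unfolded protein and amino acid stress genes (2 and 2 adjusted over the list alone). E2F and G1/S genes had 0 called of 35 in limma, with 6 lower at an unadjusted p below 0.05, and G2/M and mitosis genes 1 lower of 28. In heat shock genes HSPA8 was the 1 of 16 that fell, and NF-kappaB target genes had 1 lower of 15 (2 higher and 5 lower adjusted over the list alone).

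In total limma called 268 genes in AMO1 at 100 nM, 53 higher and 215 lower, with 24 and 53 by 2-fold or more. Centring gave 241 higher and 338 lower, and quantile normalization 205 and 254. The count depended on single libraries, being 942 (60 higher and 882 lower) without DMSO replicate 3. It was 103 without DMSO replicate 1, 110 without DMSO replicate 2, 136 without 100 nM replicate 1 and 100 without 100 nM replicate 2. It was 6 with only the 6 libraries compared in the fit, 3 of them among the 268. TEX19 and SNHG12 were still called there, and the other genes named above as called at this dose were not, with an adjusted p from 0.0629 for TAF1D to 0.111 for MGAT3 (GDF15 0.0742, POLR2A 0.0752, HSPA8 0.0899).

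At 1000 nM in AMO1, GDF15 rose from 28.9 ± 9.94 to 219 ± 15.5 FPKM (log2 change 2.94 ± 0.20, 3.15 after centring, adjusted p = 2.38e-08), and HIST2H2BE rose from 4.67 ± 1.81 to 34.2 ± 5.68 FPKM (log2 change 2.67 ± 0.21, 2.88 after centring, adjusted p = 8.83e-08). METTL1 fell from 45.2 ± 13.1 to 6.83 ± 0.566 FPKM (log2 change -2.52 ± 0.19, -2.31 after centring, adjusted p = 8.06e-08). ZBTB32, a transcriptional repressor of lymphoid cells, fell from 34.3 ± 4.87 to 5.45 ± 0.517 FPKM (log2 change -2.45 ± 0.17, -2.24 after centring, adjusted p = 2.38e-08). CIITA, the activator of MHC class II genes, fell from 25.7 ± 4.85 to 5.70 ± 0.118 FPKM (log2 change -1.98 ± 0.15, -1.77 after centring, adjusted p = 8.06e-08). MYC fell from 41.6 ± 18.01 to 12.5 ± 1.96 FPKM (log2 change -1.59 ± 0.29, -1.38 after centring, adjusted p = 0.00124), and IRF4 fell from 32.8 ± 1.30 to 20.3 ± 1.53 FPKM (log2 change -0.67 ± 0.15, -0.46 after centring, adjusted p = 0.00509). HSPA8 fell from 233 ± 34.0 to 48.9 ± 14.5 FPKM (log2 change -2.26 ± 0.22, -2.05 after centring, adjusted p = 2.87e-06). HNRNPDL fell from 150.4 ± 33.1 to 36.2 ± 1.35 FPKM (log2 change -2.00 ± 0.15, -1.79 after centring, adjusted p = 7.44e-08).

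Further large falls, main and centred values, were TEX19 (-2.37, -2.16), SH3BP5 (-2.01, -1.804), SNHG12 (-1.93, -1.72) and CUTC (-1.84, -1.64). Further rises were ZNF580 (1.98, 2.18), SMIM14 (1.85, 2.06), TMEM129 (1.63, 1.83), UCN (1.60, 1.81), POLR2A (1.59, 1.795) and IER3 (1.58, 1.79). The IRF4 call ended after quantile normalization (adjusted p = 0.0591). CDK7 fell from 12.0 ± 2.65 to 7.39 ± 1.66 FPKM (log2 change -0.63 ± 0.20, -0.42 after centring, adjusted p = 0.0335). The call ended after centring (adjusted p = 0.143) and quantile normalization (0.284), without the filter (0.0576), with only the 6 libraries compared (0.0849), and without DMSO replicate 2 or 3 or 1000 nM replicate 1 or 3 (up to 0.134). Not called were E2F1 (-0.24, adjusted p = 0.584), CDKN1A (0.40, 0.277), MCL1 (0.20, 0.421), CCNH (-0.37, 0.432), MNAT1 (-0.17, 0.733) and ABCB1 (-0.19, 0.602). After centring CDKN1A (0.61, adjusted p = 0.0438) and MCL1 (0.40, 0.0347) were called higher, and without DMSO replicate 3 E2F1 was called lower (-0.59, 0.0484). After quantile normalization E2F1 (0.06), MNAT1 (0.11) and ABCB1 (0.06) turned positive, the last pair also after centring (0.03 and 0.02).

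Of 22 p53 target genes 10 rose and 1 fell (the same counts adjusted over the list alone), with SESN1 (1.01) and GDF15 (2.94) higher and MDM2, a ubiquitin ligase, lower (-0.79). The list averaged 0.67 above other genes (camera adjusted p = 5.21e-11, and adjusted p = 0.328 with an estimated correlation). 16 of 29 MYC target genes fell (17 adjusted over the list alone), such as PPAN (-1.17) and CAD (-1.04), at -0.36 (adjusted p = 1.75e-06). 12 of 28 G2/M and mitosis genes fell (15 lower and 1 higher adjusted over the list alone), such as TTK (-1.68) and AURKB (-1.09), at -0.34 (adjusted p = 3.71e-04). Of the E2F and G1/S genes 12 of 35 fell (16 adjusted over the list alone), such as UNG (-1.06) and CDT1 (-0.74), at -0.22 (adjusted p = 0.00225). The myeloma and plasma cell list had 9 of 24 lower (13 adjusted over the list alone), such as SLAMF7 (-1.17), at -0.29 (adjusted p = 0.00944). Immediate early genes had 5 higher, such as BTG1 (0.67), and 3 lower, such as KLF2 (-1.70), of 20 (5 and 4 adjusted over the list alone), at 0.23 (adjusted p = 0.00944). Each of these calls after the p53 list was lost with an estimated correlation (adjusted p at least 0.813 with an estimated correlation).

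5 of 16 heat shock genes fell (5 adjusted over the list alone), such as DNAJA1 (-1.06), at -0.28 (adjusted p = 0.0470). Ribosomal protein genes lay 0.19 above other genes (adjusted p = 0.0470, median change -0.03) and mitochondrial respiration genes 0.20 (adjusted p = 0.0314). Limma called none of the 32 and 25 members (0 of either at an unadjusted p below 0.05). These 3 were lost too (adjusted p at least 0.813 with an estimated correlation), so none of the 9 at this dose held with it. Fry called 6 of them. Without DMSO replicate 1 or 1000 nM replicate 1 or 3 the heat shock call ended (adjusted p = 0.0991, 0.0606 and 0.0612), as it did after centring (0.0670), with a minimum mean of 5 FPKM (0.0620) and with only the 6 libraries compared (0.107). It also ended without any single XG1 library except 100 nM replicates 1 and 2, and without AMO1 100 nM replicate 2 or 3, through the pooled spread (up to 0.0576). Those of the ribosomal protein (0.977, 0.192 and 0.0754) and respiration lists (0.463, 0.0856 and 0.0684) ended without DMSO replicate 3 or 1000 nM replicate 2 or 3. Both of these also ended without the filter (0.185 and 0.0828) and with only the 6 libraries compared (0.0512 and 0.0629). The ribosomal call ended with a pseudocount of 5 (0.0631), after quantile normalization (0.483) and without XG1 DMSO replicate 1 or 3 or AMO1 100 nM replicate 2 (up to 0.0505), and the myeloma call with a pseudocount of 0.1 (0.0534). DNA repair (0.00490) and cholesterol synthesis genes (0.0261) were called lower by camera without the filter. Without a camera call, 7 of 21 unfolded protein and amino acid stress genes fell, such as HERPUD1 (-1.67), and 2 rose, SESN2 (1.48) and PPP1R15A (0.60). Lower were also 7 of 19 cholesterol synthesis genes such as INSIG1 (-1.09), 6 of 15 NF-kappaB target genes such as BIRC3 (-1.29). So were 5 of 19 DNA repair genes such as MSH6 (-1.07) and 3 of 19 apoptosis regulators. Lower too were 3 of 19 glycolysis and 3 of 25 transcription CDK and TFIIH genes. The last 3 shares were about that of all genes (1874 of 12204) or below. In these 6 lists the lower counts adjusted over the list alone were 8, 7, 5, 3, 4 and 3, and in the stress list 7.

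Limma called 2091 genes in AMO1 at 1000 nM, 217 higher and 1874 lower, with 53 and 336 by 2-fold or more. The median log2 change of all genes was -0.18 (0.02 after centring). The split was 758 higher and 1215 lower after centring and 861 and 1011 after quantile normalization, but 211 and 1906 with spike-in scaling. The count was 1248 without DMSO replicate 1, 1187 without DMSO replicate 2, 1237 without 1000 nM replicate 1 and 1246 without 1000 nM replicate 2. Few marker genes of other cell types were measured. Of 6 T cell and myeloid markers limma called LYZ in XG1 at 1000 nM (-0.78, not called after quantile normalization, with a pseudocount of 0.1 or with only the 6 libraries compared, adjusted p = 0.0784, 0.130 and 0.0699). Of 7 stromal and epithelial markers KRT18 in AMO1 at 1000 nM (-0.77, not called with a pseudocount of 5, adjusted p = 0.106). Of 9 drug transporter genes ABCC1, an efflux pump, was the 1 lower in AMO1 at 1000 nM (-0.72, adjusted p = 0.0300, and 1 adjusted over the list alone), a call that ended without any single one of the 6 libraries (adjusted p up to 0.106), after centring (0.0626) and quantile normalization (0.0755), and without the filter (0.0530). Camera did not call that list there (adjusted p = 0.649).

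**Figure D3:**
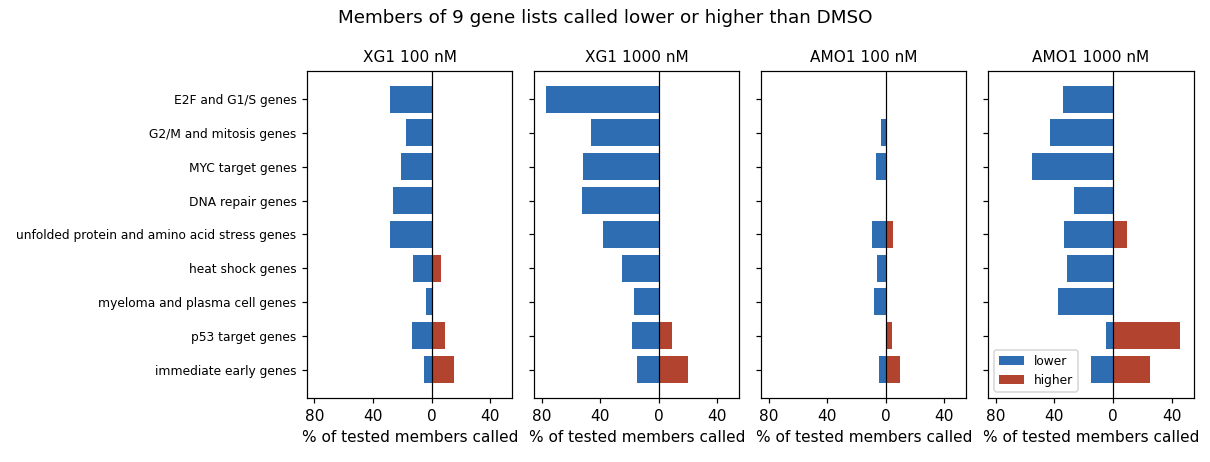
Percent of the tested members of 9 gene lists called higher or lower than DMSO (horizontal bars, limma adjusted p below 0.05) in the 4 comparisons. At 1000 nM, 27 of 35 E2F and G1/S genes were lower in the XG1 libraries and 12 in AMO1, and 10 of 22 p53 target genes were higher in AMO1.

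Few genes were called between 100 and 1000 nM. In the XG1 libraries C19orf73 fell from 3.25 ± 1.23 to 0.146 ± 0.0772 FPKM (log2 change -1.85 ± 0.25, -1.67 after centring, adjusted p = 0.00625). CTHRC1, a secreted glycoprotein, fell from 12.5 ± 3.78 to 4.44 ± 1.29 FPKM (log2 change -1.30 ± 0.21, -1.12 after centring, adjusted p = 0.0185). OR2B6 (-1.95, -1.77 after centring) and TMEM147-AS1 (-1.21, -1.03) fell too. MYC, from 26.5 ± 0.196 to 15.8 ± 5.69 FPKM, was not called between the doses (-0.77, adjusted p = 0.212), nor was CDK7 (-0.32, 0.418). In AMO1 METTL1 fell from 19.9 ± 2.57 to 6.83 ± 0.566 FPKM (log2 change -1.41 ± 0.19, -1.31 after centring, adjusted p = 0.00283). ZBTB32 fell from 13.3 ± 2.37 to 5.45 ± 0.517 FPKM (log2 change -1.15 ± 0.17, -1.04 after centring, adjusted p = 0.00469), and CIITA from 11.8 ± 0.593 to 5.70 ± 0.118 FPKM (log2 change -0.94 ± 0.15, -0.84 after centring, adjusted p = 0.0138). GDF15 rose from 104 ± 14.4 to 219 ± 15.5 FPKM (log2 change 1.07 ± 0.20, 1.17 after centring, adjusted p = 0.0220). SCGB3A2 (1.46), DYRK1B (0.94) and DYDC1 (0.92) also rose, YEATS4 (-0.96) and CDCA7 (-0.94) fell, and MYC was not called (-0.80, 0.306).

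Limma called 17 genes lower and 0 higher between the doses in XG1 and 4 higher and 18 lower in AMO1, beside 1995 and 1282 of 12204 genes in either direction at an unadjusted p below 0.05. The median log2 change of all genes was -0.18 in XG1 and -0.11 in AMO1. The higher and lower counts after centring were 0 and 8 in XG1 and 9 and 26 in AMO1, with 11 and 11 in AMO1 after quantile normalization. With only the 6 libraries compared in the fit, none of the XG1 genes named here was called (adjusted p from 0.0983 to 0.378), and in AMO1 METTL1, GDF15, CIITA and DYDC1 were but SCGB3A2, ZBTB32, YEATS4, DYRK1B and CDCA7 (up to 0.0748) were not. A pseudocount of 0.1 ended the OR2B6, CTHRC1, ZBTB32, CIITA, DYRK1B, DYDC1 and CDCA7 calls (up to 0.1002), and one of 5 that of SCGB3A2 (0.102). The GDF15 call ended without the filter (0.0530) and without trend and robust estimation (0.0645), and that of CDCA7 in both cases and after quantile normalization (up to 0.104). Of the named calls, those for C19orf73 in XG1 and METTL1 in AMO1 held without any single library. In XG1 the count was 1 without 1000 nM replicate 2, where OR2B6, CTHRC1 and TMEM147-AS1 were lost (adjusted p up to 0.0734). It was 310 without 1000 nM replicate 3, 38 without 1000 nM replicate 1, 8 without 100 nM replicate 1 (CTHRC1 lost) and 37 without 100 nM replicate 3. Libraries outside the comparison moved it through the pooled spread, to 45 and 39 without XG1 DMSO replicates 1 and 3, 11, 8 and 31 without AMO1 DMSO replicates 1, 2 and 3, 11, 10 and 8 without AMO1 100 nM replicates 1, 2 and 3, and 10, 8 and 8 without AMO1 1000 nM replicates 1, 2 and 3. In AMO1 it was 2 without 100 nM replicate 3 or 1000 nM replicate 3, which each ended the ZBTB32 call (adjusted p up to 0.0864). It was 4 without 100 nM replicate 1 or 1000 nM replicate 1, 7 without 1000 nM replicate 2 and 118 without DMSO replicate 3, which is outside the comparison. The GDF15, DYRK1B, DYDC1, YEATS4 and CDCA7 calls ended without any one of the 6 libraries (adjusted p up to 0.143, 0.159, 0.175, 0.166 and 0.330), and those of CIITA (0.107) and SCGB3A2 (0.132) without any but 100 nM replicate 2.

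**Figure D4:**
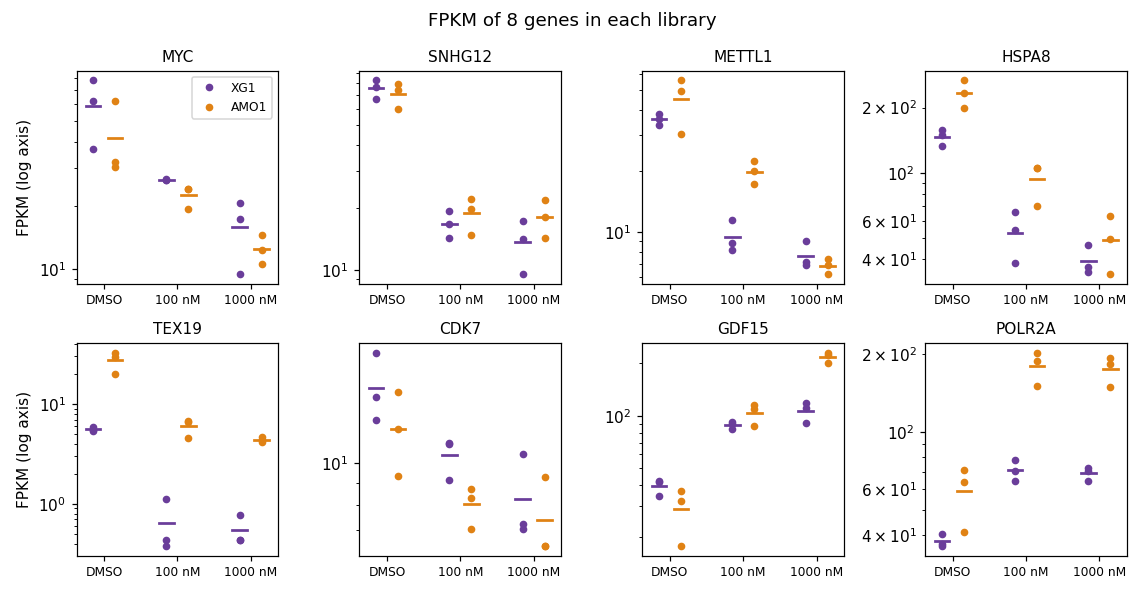
Expression in FPKM (log axis) of MYC, SNHG12, METTL1, HSPA8, TEX19, CDK7, GDF15 and POLR2A in DMSO, 100 nM and 1000 nM libraries of each line, with points for single libraries and a short bar at each group mean. In AMO1 METTL1 went from 45.2 ± 13.1 to 6.83 ± 0.566 FPKM and GDF15 from 28.9 ± 9.94 to 219 ± 15.5 FPKM between DMSO and 1000 nM.

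Genes called at 100 nM were compared with those called at 1000 nM of the same line. In the XG1 libraries 159 of the 321 genes higher and 460 of the 486 lower at 100 nM were called that way at 1000 nM too, and in AMO1 44 of 53 and 207 of 215. GDF15, POLR2A and IER3 were higher and SNHG12, TEX19 and HSPA8 lower at both doses in AMO1. Independent lists of those sizes would share 6.10 and 76.5 genes in XG1 and 0.942 and 33.0 in AMO1. Both doses share their DMSO libraries. In 50 simulations of unchanged groups the shared number averaged 0. There all libraries, DMSO included, were drawn anew as independent noise around the line's mean, so hardly any adjusted call could arise. That 0 therefore does not show how many shared calls come from the real DMSO libraries. Across genes, which are not independent replicates, the covariance of the log2 changes was 0.171 in XG1 and 0.153 in AMO1, beside 0.0653 and 0.0626 in the simulations, a difference of 0.106 and 0.0900. Splitting 3 DMSO libraries would leave a part with 1, so part of the excess may come from the shared controls. After centring the shared counts were 431 higher and 670 lower in XG1 and 197 and 310 in AMO1, and after quantile normalization 619 and 686, and 189 and 237. Without DMSO replicate 3 the AMO1 total rose from 251 to 877. It was 94 without DMSO replicate 1, 104 without DMSO replicate 2, 129 without 100 nM replicate 1, 91 without 100 nM replicate 2 and 3 with only the libraries compared in the fit. The XG1 total of 619 was 309 without DMSO replicate 1, 296 without DMSO replicate 2, 325 without 100 nM replicate 1 and 357 without 100 nM replicate 3.

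The lines shared many of their calls at 1000 nM. SNHG12, METTL1, TEX19, HSPA8 and MYC were lower and GDF15, POLR2A, SMIM14, IER3 and JUNB higher in both. Together 64 genes were higher in both lines and 927 lower, beside 4.13 and 295 for independent lists of those sizes, and 10 and 105 by 2-fold or more. Genes called in opposite directions numbered 2 and 4. The lines share no control library. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.345 at 1000 nM and 0.237 at 100 nM (Spearman's rho 0.471 and 0.371). After centring the shared counts were 252 higher and 567 lower, and after quantile normalization 368 and 473. Without AMO1 DMSO replicate 3 the total rose from 991 to 1433. It was 604 without XG1 DMSO replicate 1, 645 without XG1 1000 nM replicate 2, 644 and 623 without AMO1 DMSO replicates 1 and 2, 639 without AMO1 1000 nM replicate 1 and 449 with only the groups compared in the fit. The JUNB call in AMO1 ended without DMSO replicate 2 (adjusted p = 0.0632).

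The responses of the lines were compared directly by the difference of their log2 changes, XG1 minus AMO1. At 1000 nM ZBTB32 (2.43 ± 0.24, adjusted p = 2.51e-05) and CIITA (1.95 ± 0.22, 1.18e-04), both lower in AMO1, were under 1 FPKM in the XG1 libraries. GDF15 rose less in XG1 (1.41 against 2.94, difference -1.53 ± 0.28, adjusted p = 0.0101). HIST2H2BE (0.42 against 2.67, adjusted p = 8.05e-04) and SESN2 (-0.07 against 1.48, adjusted p = 0.00140) rose in AMO1 and were not called in XG1. BBC3, a cell death gene, went -0.94 against 0.60 (adjusted p = 0.00598). HEMGN, a hematopoietic nuclear protein, and GBGT1 fell in XG1 (-1.99 and -2.27) and were under 1 FPKM in AMO1. The HEMGN difference was not called with a pseudocount of 0.1 (adjusted p = 0.0594). MYC (-0.24 ± 0.41, adjusted p = 0.917) and CDK7 (-0.16 ± 0.28, 0.919) showed no called difference, nor did IRF4 (0.81 ± 0.22, 0.0930) and E2F1 (-1.003 ± 0.35, 0.236). The IRF4 difference was called after centring (0.81, adjusted p = 0.0431), with a pseudocount of 5 (0.61, 0.0404) and without trend and robust estimation (0.81, 0.0456).

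By list at 1000 nM the p53 target genes differed by -0.57 log2 (camera adjusted p = 9.62e-08), with 4 of 22 called lower in XG1 than in AMO1 (8 adjusted over the list alone). The E2F and G1/S genes differed by -0.38 (adjusted p = 2.86e-07), with 7 lower adjusted over the list alone and 0 over all genes in limma (11 at an unadjusted p below 0.05). Myeloma and plasma cell genes differed by 0.30 (adjusted p = 0.0116), but 10 of the 24 were below 1 FPKM in the XG1 libraries, where little or no fall can appear, so a fall in AMO1 alone makes that difference positive. DNA repair genes differed by -0.26 (adjusted p = 0.0175) and unfolded protein and amino acid stress genes by -0.31 (adjusted p = 0.00701). With an estimated correlation none held (adjusted p = 0.759 with an estimated correlation for the p53 list and 0.932 for the stress list). Without XG1 1000 nM replicate 2 the myeloma call ended (adjusted p = 0.244), as it did after quantile normalization (0.0960) and with a pseudocount of 0.1 (0.0593). Without XG1 1000 nM replicate 3 the stress call ended (0.116). MYC targets were called higher without AMO1 DMSO replicate 3 (0.0177), ribosomal protein genes lower without XG1 1000 nM replicate 2 (0.0480) or AMO1 DMSO replicate 1 (0.0384), and drug transporters higher without XG1 1000 nM replicate 2 (0.0377) or AMO1 1000 nM replicate 3 (0.0427).

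At 100 nM DHRS9 differed by -1.73 ± 0.27 (adjusted p = 0.0152), falling in XG1 and under 1 FPKM in AMO1. Its call held without any single library but not with a pseudocount of 0.1 (adjusted p = 0.138). Of the other named genes GBGT1 (-1.49 ± 0.26, adjusted p = 0.0164) was lost without AMO1 DMSO replicate 1, AMO1 100 nM replicate 1 or XG1 DMSO replicate 2 (adjusted p up to 0.0654) and with a pseudocount of 0.1 (0.424). Camera called 5 lists, E2F and G1/S (-0.36, adjusted p = 1.85e-07), unfolded protein and amino acid stress (-0.39, 1.08e-05), p53 targets (-0.27, 0.00515), G2/M and mitosis (-0.18, 0.00932) and DNA repair (-0.23, 0.0354), none of them with an estimated correlation (adjusted p = 0.810 with an estimated correlation). The DNA repair call ended without XG1 DMSO replicate 3, XG1 100 nM replicate 1 or 3, or AMO1 DMSO replicate 1 or 100 nM replicate 1 (adjusted p up to 0.149) and with a pseudocount of 0.1 (0.0505). The G2/M call ended without XG1 100 nM replicate 1 (0.0552). Ribosomal protein genes were called lower after centring (0.0494), without the filter (0.0302) and without XG1 DMSO replicate 1, XG1 100 nM replicate 3 or AMO1 DMSO replicate 1 (down to 0.00357), but their difference was 0.05 after quantile normalization. MYC targets were called lower without AMO1 DMSO replicate 2 (0.0368) or 100 nM replicate 1 (0.0434), and interferon genes without AMO1 DMSO replicate 3 (0.0433). In all, 83 genes differed at 1000 nM, 40 higher and 43 lower in XG1 than in AMO1. At 100 nM 19 did, 11 higher and 8 lower (25 and 47 after centring, 33 and 43 after quantile normalization, and 9 and 3 with spike-in scaling). Without 1 library the count at 100 nM was 12 (XG1 DMSO replicate 1), 4 (XG1 DMSO replicate 2), 8 and 10 (XG1 100 nM replicates 1 and 3), 11, 3 and 35 (AMO1 DMSO replicates 1, 2 and 3) 3 and 6 (AMO1 100 nM replicates 1 and 2) and, outside the comparison, 29 (XG1 1000 nM replicate 2) and 10, 10 and 11 (AMO1 1000 nM replicates 1, 2 and 3). At 1000 nM it was 55 and 42 (XG1 DMSO replicates 1 and 2), 53 (XG1 1000 nM replicate 1), 55, 54 and 165 (AMO1 DMSO replicates 1, 2 and 3) and 51 and 42 (AMO1 1000 nM replicates 1 and 2).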

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

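The tests of a difference between the lines were planned before the data were examined. Each result here stands out because the response of the XG1 libraries differed from that of AMO1 in a direct test, with values given as the XG1 log2 change minus the AMO1 log2 change. At 100 nM 19 genes differed. Named among them were LBX2 (1.54), KCNJ6 (1.45), WDR78 (1.43), HCG27 (1.39) and ZBTB32 (1.39), higher in XG1, and DHRS9 (-1.73), GBGT1 (-1.49), HEMGN (-1.47), C1orf186 (-1.31), CYB561D2 (-1.23) and RRM2 (-0.98), lower. Camera at its preset correlation gave a difference for E2F and G1/S (-0.36), G2/M and mitosis (-0.18), p53 target (-0.27), DNA repair (-0.23) and unfolded protein and amino acid stress genes (-0.39). None of these 5 list calls held with an estimated correlation (adjusted p at least 0.810 with an estimated correlation), and fry called 0 lists. The G2/M and DNA repair calls also ended in the cases given above. RRM2, a subunit of ribonucleotide reductase, went -0.85 in XG1 against 0.13 in AMO1 (limma adjusted p = 0.0483), and its call ended without any 1 of 11 of the 12 libraries (adjusted p up to 0.135). With only the 12 libraries compared in the fit RRM2 (0.114) and HEMGN (0.0638) were not called, and with a pseudocount of 0.1 ZBTB32 (0.232), WDR78 (0.190), HCG27 (0.108), DHRS9 (0.138), GBGT1 (0.424), HEMGN (0.219), C1orf186 (0.3196), CYB561D2 (0.0923) and RRM2 (0.0796) were not. The HEMGN, C1orf186, CYB561D2 and RRM2 calls also ended without the filter, with a minimum mean of 5 FPKM and with spike-in scaling (adjusted p up to 0.0746). With a block for the replicate number 1 gene was called, and those calls that held without any single library were DHRS9 alone among the 11 named.

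At 1000 nM 83 genes differed. They included CCDC107 (2.88), ZBTB32 (2.43), CIITA (1.95) and PPAPDC1B (1.76), higher in XG1, and SAPCD1 (-2.64), PYCARD-AS1 (-2.34), HIST2H2BE (-2.26), GBGT1 (-2.19), HEMGN (-1.99), GADD45A (-1.91), ATF3 (-1.73), SESN2 (-1.56), BBC3 (-1.54) and GDF15 (-1.53), lower. By camera at its preset correlation E2F and G1/S (-0.38), p53 target (-0.57), DNA repair (-0.26) and unfolded protein and amino acid stress genes (-0.31) lay lower and myeloma and plasma cell genes (0.30) higher. None of these 5 list calls held with an estimated correlation (adjusted p at least 0.759 with an estimated correlation), and fry called 0 lists. Of the 24 myeloma and plasma cell genes 10 were below 1 FPKM in the XG1 libraries, where little or no fall can appear, so a fall in AMO1 alone makes that list's difference positive. Its call and that of the stress list ended in the cases given above. GADD45A, a stress response gene, went -0.74 in XG1 and 1.17 in AMO1, and ATF3 -0.99 and 0.74. CCDC107 went 1.79 and -1.08, PPAPDC1B 1.40 and -0.36, and PYCARD-AS1 -1.62 and 0.72. The calls named here held without any single library except those of CCDC107 (adjusted p up to 0.0742, 9 libraries), SAPCD1 (0.111, 11 libraries), GADD45A (0.0608, without AMO1 1000 nM replicate 2 or XG1 DMSO replicate 1 or 2) and ATF3 (0.0700, 6 libraries). A pseudocount of 0.1 ended those of CCDC107 (0.175), SAPCD1 (0.118), PYCARD-AS1 (0.0725), HEMGN (0.0594) and ATF3 (0.0637), and SAPCD1 was not called without the filter (0.0526) either.

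Chance was tested in another fit than the one that gave 19 and 83, made of the 12 libraries compared with values centred within each line, where the real grouping called 14 genes at 100 nM and 59 at 1000 nM. Treated libraries were exchanged between the lines, and DMSO libraries likewise. The highest of the other splits called 2 in either case, and 1 of 100 splits, the real grouping, reached the real value. That argues against an arbitrary grouping of these libraries as the source of the 14 and 59. Chance between cultures is not excluded, because replicates may be technical and libraries of lines with such different levels are not fully exchangeable. Several of these genes were near the floor in 1 line (ZBTB32 and CIITA in XG1; DHRS9, GBGT1, HEMGN, C1orf186 and SAPCD1 in AMO1), where a fall can hardly appear.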

How the results depend on the processing

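All settings named here were chosen before the data were examined. Under none of them did a gene or list called before or after the change turn its direction, though uncalled ones did: 10 gene results after centring, 12 after quantile normalization, 1 each with a pseudocount of 0.1 and spike-in scaling and 46 without 1 library; and 10 list results with a minimum mean of 5, 9 without the filter, 7 and 8 with pseudocounts of 0.1 and 5, 8 after quantile normalization and 43 without 1 library. Counts are of genes called, in the order XG1 100 nM, AMO1 100 nM, dose in XG1, dose in AMO1, line difference at 100 and 1000 nM, where they moved by over 1.5 times; the cause was not tested. They were 1593, 579, 8, 35, 72 and 245 after median centring, where genes shared between doses were 1101 in XG1 and 507 in AMO1. After quantile normalization they were 1878, 459, 10 (XG1 dose), 76 and 216 (line differences), with 1305 and 426 shared between doses. A pseudocount of 0.1 gave 137 (AMO1 100 nM), 13 (AMO1 dose), 6 and 27 (line differences) and 126 shared between AMO1 doses, and one of 5 gave 453, 60 (XG1 dose), 37 (AMO1 dose), 67 and 201 (line differences) and 424 shared between AMO1 doses. A minimum mean of 5 FPKM gave 31 (XG1 dose) and 4 (line difference, 100 nM), spike-in scaling 32 and 12 for these, and no filter 10 for the latter. Fitting only the groups compared left 1197 in XG1 at 1000 nM, 6 in AMO1 at 100 nM, 2 and 13 between doses in XG1 and AMO1, 54 for the line difference at 1000 nM, 449 shared between lines and 3 between AMO1 doses. At 2-fold or more 115 genes were shared between lines. Of 36 list calls by camera, 0 held with an estimated correlation, and 4, 5, 0, 6, 0 and 0 (XG1 at 100 and 1000 nM, AMO1 likewise, line differences) were among the 4, 8, 0, 9, 0 and 0 of fry, 21 in all. The replicate numbers did not pair the libraries: correlations of same-numbered libraries' deviations were -0.124 to 0.0908, 0 of 18 pairs were above 0.1, and 2 of 18 libraries correlated best with their own number. With the replicate block counts were 486, 123, 4, 4, 1 and 38, with 637 shared between lines and 360 and 112 between doses in XG1 and AMO1; no paired analysis was possible for the lines in DMSO because the numbers lie within a line. Without 1 of the libraries compared the counts ranged from 396 (without DMSO replicate 2) to 613 in XG1 at 100 nM, 1108 (DMSO replicate 1) to 2561 (1000 nM replicate 3) at 1000 nM, 100 (100 nM replicate 2) to 942 (DMSO replicate 3) in AMO1 at 100 nM, and 1187 (DMSO replicate 2) to 3031 (DMSO replicate 3) at 1000 nM. Between doses they ranged from 1 (1000 nM replicate 2) to 310 (1000 nM replicate 3) in XG1 and 2 (100 nM or 1000 nM replicate 3) to 17 in AMO1. Without a library outside the comparison they rose to 1189 and 118 (AMO1 DMSO replicate 3; XG1 100 nM, AMO1 dose). For the line difference they were 3 (AMO1 DMSO replicate 2 or 100 nM replicate 1) to 35 (AMO1 DMSO replicate 3) at 100 nM and 42 (AMO1 1000 nM replicate 2 or XG1 DMSO replicate 2) to 165 (AMO1 DMSO replicate 3) at 1000 nM, and between the lines in DMSO 6961 to 7744. Shared genes were 604 (XG1 DMSO replicate 1) to 1433 (AMO1 DMSO replicate 3) between lines, and between doses 296 (DMSO replicate 2) to 625 in XG1 and 91 (100 nM replicate 2) to 877 (DMSO replicate 3) in AMO1, and list calls were 33 to 36. Each library that moved a count of calls by over 1.5 times, outside ones too, is named with its comparison. Of 285 called gene results, 40 were lost with a pseudocount of 0.1, 8 with one of 5, 32 without the filter, 4 of 255 with a minimum mean of 5, 13 after centring, 23 after quantile normalization, 11 with spike-in scaling, 7 without trend and robust estimation, 75 with only the groups compared and 58 of 269 with the block, 382 of 1866 gene results without 1 of the libraries compared and 104 of 3264 without 1 of the others. Depth is unknown, so what it limits could not be set, and count models were not run because the values are not counts.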

Other observations

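The 7 gene lists of this part, both tests of the label XG1 and the test for XG1 RNA in AMO1 DMSO replicate 3 were chosen after the results were seen. The other tests were written down before their results were seen. Host genes of small nucleolar RNAs, whose introns carry these guides of RNA modification, were followed up after SNHG12, SNHG3, TAF1D and HSPA8 had been seen among the largest falls. The list includes them, so its counts are no independent evidence of a direction. Of 30 tested, limma called 14 lower in the XG1 libraries at 100 nM, 19 at 1000 nM, and 8 and 17 in AMO1. SNHG1, SNHG3, SNHG7, SNHG12, TAF1D, EIF4A2 and HSPA8 were lower in all 4 comparisons, while SNHG5, SNHG6, RPL7A and EIF4A1 were called in none. Camera did not call the list with an estimated correlation (adjusted p = 0.0783, 0.178, 0.198 and 0.203 with an estimated correlation). Of 30 RNA splicing factor genes 11 and 17 were lower in the XG1 libraries and 8 and 14 in AMO1 (adjusted p = 0.101, 0.178, 0.327 and 0.203 with an estimated correlation), and CLK4 was higher in XG1 at 1000 nM. SRSF3, a splicing factor, fell by 1.44 and 1.57 log2 in XG1 and by 0.94 and 1.73 in AMO1.

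Of 18 tRNA modification and ribosome assembly genes, 9 and 10 were lower in the XG1 libraries and 3 and 14 in AMO1 (adjusted p = 0.0783, 0.178, 0.198 and 0.203 with an estimated correlation). Of 17 ATF4 pathway genes, which serve amino acid supply and the stress response, 7 and 12 were lower in XG1. In AMO1 2 were lower and 1 higher at 100 nM, and 7 lower and 2 higher, SESN2 and ATF3, at 1000 nM (adjusted p = 0.0783, 0.178, 0.679 and 0.765 with an estimated correlation). The list's difference between the lines was -0.48 at 100 nM and -0.53 at 1000 nM (adjusted p = 0.212 and 0.368 with an estimated correlation). Of the 18 tested of 20 erythroid genes, KLF1 and HEMGN included, 2 were lower in the XG1 libraries at 100 nM and 5 at 1000 nM (adjusted p = 0.350 and 0.502 with an estimated correlation). Among them were KLF1, an erythroid transcription factor (-1.56 and -1.92), and HEMGN (-1.34 and -1.99). In AMO1 CIITA was the 1 of 12 antigen presentation genes lower at 100 nM, joined by TAP2 at 1000 nM, and TNFRSF17, IRF4 and SLAMF7 were the 3 of 10 plasma cell genes lower at 1000 nM. These lists share members with the fixed ones, such as HSPA8, DKC1, NCL and NOP56, and were not rerun under the other settings.

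Plasma cell genes were low in the libraries labelled XG1, 9 of 10 at under 5% of their AMO1 mean in DMSO and 5 of 10 under 1 FPKM in all 9 libraries. Scaling by the authors' normalization is argued against as their source, because the median difference between the lines over all genes was -0.0819 log2. Cells of another lineage remain a candidate explanation, since 12 of 18 erythroid genes (without KLF1 and HEMGN) were at 10 FPKM or more in all 9 of these libraries. Outside the rule, GATA2, a blood progenitor factor, ranged from 28.7 to 85.7 FPKM in them against at most 0.378 in AMO1. HBB, also outside, was at 14.6 FPKM or more against at most 2.86. That the line named XG1 itself has this expression stays open, since no other library of that line was compared.

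AMO1 DMSO replicate 3 stood apart from its group, with 687 and 669 genes over 2-fold apart from replicates 1 and 2, which differed at 258. A shift of the whole library is argued against as the whole cause, because after centring 350 and 343 genes were still that far apart, the lower of them about 1.35 times the highest number of the other pairs within AMO1 groups. Pairs within XG1 groups differed at 252 to 431 genes after centring, so replicate 3 then stood apart within AMO1 but not from all libraries. RNA of the XG1 cultures is argued against, because 17 genes abundant there reached a median of 0.207% of their XG1 level (0.165% in replicates 1 and 2), and so is an inhibitor-treated library under a DMSO label, because 326 genes that the inhibitor lowered in XG1 had moved a share of 0.0446 of the way to AMO1 at 100 nM (-0.02 against -0.41 log2). MYC was at 62.4 FPKM in replicate 3 and 30.4 and 32.0 in replicates 1 and 2, and E2F1 at 12.7 against 26.3 and 28.6. No biological explanation was tested.

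Among 277 antisense-named transcripts, limma called 15 higher and 37 lower in the XG1 libraries and 18 higher and 11 lower in AMO1 at 1000 nM, higher more often than other genes (odds ratio 3.09 and 4.09, Fisher's exact test adjusted p = 3.56e-04 and 8.81e-06). At 100 nM 19 and 8, and 6 and 1, were called (odds ratio 2.83 and 5.59, adjusted p = 2.68e-04 and 0.00121). Reads of the sense partner counted without strand are argued against as the source, because the changes of 214 pairs at 1000 nM had a Spearman correlation across genes of 0.0264 in XG1 (95% bootstrap interval -0.110 to 0.157) and 0.00354 in AMO1 (-0.130 to 0.136). Lists matched on mean expression, not on the level within a line, cannot decide whether a low level alone is the source. The antisense median lay at percentile 100 of 10000 such lists in AMO1 and 95.82 in XG1 at 1000 nM. In XG1 at 100 nM it lay at percentile 100, at 0.10 log2 (highest matched list 0.07). A biological source was not tested.

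Longer genes did not fall more at 1000 nM to the extent set in advance: over 11478 genes with an annotated span the Spearman correlation of span and log2 change was -0.0170 in the XG1 libraries and -0.0773 in AMO1, both above the limit of -0.1. The 2870 genes of shortest span in AMO1 had a median change of -0.12 log2 and the 2870 of longest span -0.21. At 100 nM, for which no limit was set, the correlation was 0.0217 in XG1 and -0.127 in AMO1, with AMO1 medians of -0.03 and -0.13, so a weak relation with span in AMO1 stays open. For comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. The real and highest other splits called 807 and 5 genes in XG1 at 100 nM, 2152 and 2 at 1000 nM, 268 and 242 in AMO1 at 100 nM, 2091 and 2 at 1000 nM, 17 and 6 between doses in XG1, 22 and 5 in AMO1, and 7652 and 1 between the lines. In each, 1 of 10 splits, the real one, reached the real value. The split that called 242 set DMSO replicates 1 and 2 with 100 nM replicate 3 against the other 3 AMO1 libraries.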
